A study of Rattus norvegicus with 33 samples.

How the data were processed

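Total RNA of 33 rat prostate samples was measured on single-colour Agilent 8x60K arrays, after labelling of 500 ng RNA with Cy3 and with RIN values of at least 8, per the labels' protocols. Per the file headers, the images were read with Agilent Feature Extraction 12.0.0.7 under protocol GE1_1200_Jun14 for array design 074036, whose grid names genome build rn4. The deposited spot values are fluorescence intensities on a linear scale, background-subtracted and detrended within each array per the file headers, and not scaled between arrays. The authors' deposited value table holds intensities of the same arrays. Set against the scanner values it is linear and not centred, each array scaled to a 75th percentile of 619.357 to 619.517, with a log correlation of at least 0.999982 and column medians of 30.8 to 49.9. How that table was made is not given in the sources used here.

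For each array log2 of the processed signal minus log2 of the array's 75th percentile over non-control spots was used. Feature Extraction's outlier spots, 413 to 969 per array, were left out, and spots of 1 probe were averaged. Of 45598 probes, 21184 were named through accessions in a RefSeq gene table, 9060 by symbol and 406 by synonym. The name in the files was kept for 5247, and 9701 had no gene name. Probes well above background on at least 3 of 33 arrays were kept (30542), and the brightest probe stood for each symbol, which left 23345 genes, 15620 of them with a gene symbol. Probes of multigene families, such as immunoglobulin segments, RT1 antigens, Ly6 genes, secretoglobins and the pseudogene Rps4x-ps1, may bind related transcripts, and their values are uncertain. Where a gene was not well above background on any array of a group, the fold is a lower bound, written "at least N-fold". It sets the mean of the brighter group against the mean, per array, of the higher of the dim signal and the lowest signal well above background.

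Group means of all 10 groups were fitted with limma 3.58.1 in R 4.3.3, with a trended, robust empirical Bayes variance and Benjamini-Hochberg adjustment within each of 19 comparisons at 0.05. The standard errors come from this fit, which shares 1 estimate of the spread between groups. The comparisons covered EB, T+E and EB+T+E against control at each age that had them, EB+T+E against each single treatment, the interactions, the controls by age and the differences of effects between ages. The rule for named genes took the 6 highest and 6 lowest log2 ratios among called genes whose arrays did not overlap between the 2 groups (3 and 3 outside the control comparisons), with a gene symbol and a signal well above background in both groups. It also took the 2 largest bounds in each direction. Further named were up to 4 members with the smallest p of each described list, and the receptors Esr1, Esr2 and Pgr. A few genes that the rule takes are not reported here. In contrasts of 4 groups the condition of no overlap could not be applied. The groups, the tests, the lists, the rule for named genes and most alternatives were chosen before the data were examined.

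The 27 gene lists were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. They cover prostate secretory and hormone-responsive genes, cell types of the prostate and its neighbours, immune cells, and pathways of growth, stress, lipids and development, each named where its result is given. Of 513 list tests 232 passed, and 113 of these are described, a choice made after their values were seen. With an estimated correlation 3 of the 232 were called. Medians with genes at their bounds differed from the medians given by up to 1.31.

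Slides 1 to 4 each held 8 arrays of several groups and slide 5 held EB 4 of PND 145, with 1 scan time per slide, so slide was fitted as a block and values were also taken within slides. Alternatives were normexp background correction (offset 50), quantile scaling, no filter or a filter of 17 arrays, and slide or replicate number as blocks. Others were a fit of only the groups compared, each array left out, the authors' deposited table, the mean of all probes, array weights, a 2-fold minimum, and other list tests. Covariates for ventral products and other tissues and a fit without 2 control arrays were added after the data were seen. The fit was tested on simulated data with 200 of 23345 genes changed. It recovered 13% (T+E, PND 100) to 29% (EB, PND 30) of genes changed by 1 on the log2 scale. For genes changed by 2 it recovered 44% (EB+T+E, PND 100) to 64% (EB, PND 30), with 0 to 6 false calls. The shifted list was found in all 7 comparisons with controls. Another split of the real arrays called 529 genes (EB, PND 30), so these rates may not hold there. Files were read with Python 3.11.15 and pandas 2.3.3, version 1.17.8 of data.table was used in R, and figures were drawn with matplotlib 3.10.9.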

Results

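RNA was measured in prostates of 33 male Sprague-Dawley rats, with 1 single-colour Agilent microarray per sample. The samples are labelled as whole prostate, while the title of the series names the dorsolateral prostate, so which lobes were taken is not settled here. Pups received estradiol benzoate (EB), a long-acting estrogen ester, at 2.5 mg/kg under the skin on postnatal days (PND) 1, 3 and 5, or vehicle. From PND 90 adult animals carried implants with testosterone and estradiol (T+E) or empty implants. The control and EB groups at PND 30 held 4 arrays each, and so did the EB group at PND 145. The control, EB, T+E and EB+T+E groups at PND 100 held 3 arrays each, as did the control, T+E and EB+T+E groups at PND 145. By the labels, 3 to 4 litters stood behind each group, so the p-values measure the spread between these samples.

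Each array carried 58717 spots, of which 61.5% to 68.9% were well above background. The 75th percentile of the signal ran from 1694 to 4737 between arrays before scaling, and 0 spots were saturated. Arrays of 1 group correlated at 0.864 (EB+T+E, PND 100) to 0.986 (control, PND 100), and the number of arrays per group limits the precision. Arrays are named by group and replicate number, as in EB 1. Beside each list stand its median, the members that rose or fell over all genes and camera's adjusted p. The number in brackets is adjusted over the list alone. Values are log2 ratios with their standard errors, and p-values are limma's, adjusted over 23345 genes. Beside a count of 0 stands, in parentheses, that at an unadjusted p under 0.05. After the data were seen, covariates for 4 ventral prostate products, Scgb1d2, Scgb2a1, Scgb1d4 and Sbp (ventral fit), and for other tissues (tissue fit) were added. So was a fit without the control array highest in seminal vesicle products at each adult age (reduced fit). They are given where a count moved by over 1.5 times. Parentheses beside a lost list call hold its adjusted p. After scaling, the median of all genes lay at -0.24 for EB+T+E against control at PND 145, -0.22 against EB and -0.16 against T+E. It was -0.14 for EB at PND 30, -0.10 for EB+T+E against T+E at PND 100 and -0.15 for the interaction at PND 145. The tests of gene lists compare a list with all other genes and so are relative to these shifts. All called genes named for a large change kept their direction within slides that held all groups compared. With 2 groups, choosing genes without overlap fixes this, and chance gives no overlap for 10% of genes with 3 against 3 arrays.

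**Figure D1:**
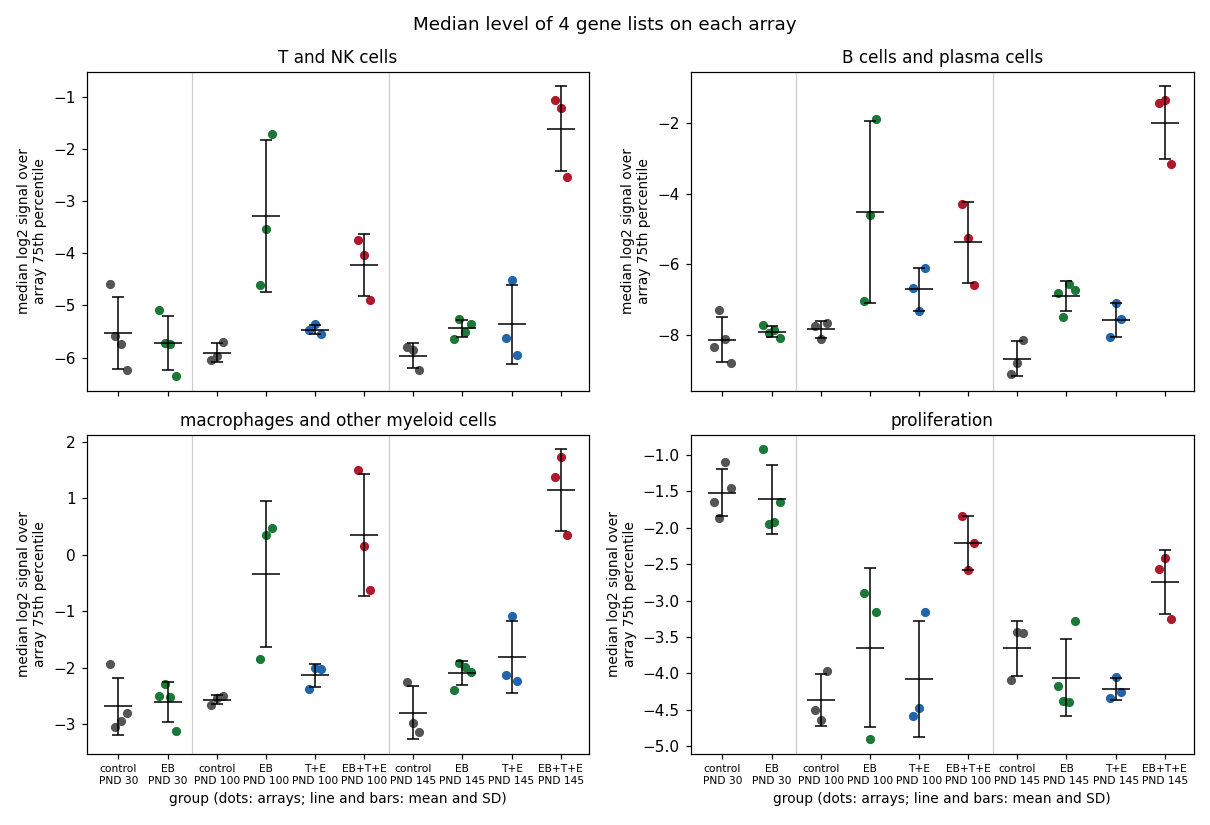
Median level of 4 gene lists on each of the 33 arrays (log2 signal over the array's 75th percentile), by group, with the group mean and SD. The T and NK cell list lay at -1.07, -1.22 and -2.54 on the EB+T+E arrays and at -5.80, -5.86 and -6.24 on the control arrays of PND 145.

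The controls show how the prostate changed with age. From PND 30 to PND 100 the transcripts of dividing cells fell, with proliferation (median -2.98, 39 [42] of 44 fell, adjusted p 3.00e-71). This list kept its call with an estimated correlation (adjusted p = 0.00627). The DNA replication helicase Mcm6 (-2.51 ± 0.30, adjusted p 2.93e-05) and the mitotic genes Bub1, Cdc20 and Kif20a (-2.78 to -3.58, SE 0.35 to 0.46, adjusted p 4.85e-05) fell. Among the largest falls were Pimreg, Depdc1 and Cenpf, which act in mitosis (-4.45 to -4.88, SE 0.63 to 0.80, adjusted p 4.85e-05 to 6.98e-04). The cell cycle repressor E2f7 and Ly6h fell to levels not well above background, at least 16.8-fold (adjusted p 1.47e-04) and at least 17.9-fold (adjusted p 4.54e-04). Angptl1, the fructose transporter Slc2a5 and the cadherin Cdh7 rose (4.04 to 5.74, SE 0.63 to 0.92, adjusted p 4.85e-05 to 0.0121). Otud7a and Spx rose from below background, at least 7.69-fold (adjusted p 0.00392) and at least 4.97-fold (adjusted p 0.00559). Lower were also fibroblasts and matrix (median -0.94, 7 [10] of 39 fell, adjusted p 5.58e-11) and nerve and ganglion (median -2.90, 0 [13] of 27 fell, adjusted p 2.37e-11). Lower too was smooth muscle (median -0.53, 0 [5] of 26 fell, adjusted p 1.31e-04), while unfolded protein response (median 0.43, 2 [3] of 27 rose, adjusted p 1.31e-04) lay higher. These 4 lists had adjusted p = 0.588 to 0.702 with an estimated correlation. The matrix genes periostin (Postn), Sparc, Col3a1 and Col5a2 fell (-1.83 to -3.32, SE 0.30 to 0.54, adjusted p 4.23e-04 to 0.0024). In all, 523 genes changed (179 higher, 344 lower), 527 with slide as a block, 319 in the tissue fit and 2232 when only these groups were fitted. Medians within slides 1, 2 and 3, with slide as a block in parentheses, were 0.39 to 0.66 (0.57) for the higher lists and -0.24 to -4.75 (-0.61 to -2.96) for the lower lists. Leaving out control 1 of PND 30 gave 350 called genes, with 17 of the 18 named. Without control 1, 2 or 3 of PND 100 it was 292, 295 or 352, with 18, 16 or 17 named.

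From PND 100 to PND 145 limma called 0 genes between controls (579), and 0 (1014) with only these arrays fitted. Lower as lists were fibroblasts and matrix (median -0.56, 0 [0] of 39 passed, adjusted p 4.36e-09) and adipocytes (median -1.71, 0 [0] of 15 passed, adjusted p 9.27e-08), at adjusted p = 0.727 with an estimated correlation. The spermatid genes Tnp2 and Prm3 were well above background on the arrays of PND 145 only, at least 46.1-fold (adjusted p 0.228) and at least 21.7-fold (adjusted p 0.497). Their values of 6.36 and 4.88 were 4.03 and 2.66 without control 2 of PND 145. Myod1 and Abcd2 were so on those of PND 100 only, at least 9.36-fold (adjusted p 1.0) and at least 4.5-fold (adjusted p 1.0). Slides 1 and 3 gave medians of -0.08 to -2.85 (-0.37 to -1.49) for the lower lists. The adipocyte shift was -0.60, adjusted p = 0.163 without control 3 of PND 100. Without control 1 of PND 100 there was 1 call. Removing control 1, 2 or 3 of PND 145 gave 2, 2 or 75.

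The EB effect at PND 30 asked what neonatal estrogen left in the young prostate. The chloride channel gene Best4 fell (-2.48 ± 0.37, adjusted p 0.00335) in 4 against 4 arrays. Sh3bgrl3, Ankrd35, the neurexin ligand Nxph3, Btg4 and the class I antigen gene RT1-A2 also fell (-1.28 to -4.63, SE 0.23 to 0.90, adjusted p 0.00335 to 0.0487). Brinp3 rose from below background, at least 5.42-fold (adjusted p 9.54e-04). The same kind of bound, without passing, was at least 3.72-fold (adjusted p 0.248) higher for Psapl1 and at least 76.0-fold (adjusted p 0.0817) and at least 3.32-fold (adjusted p 0.122) lower for Defb39 and Cfap221. Higher as lists were estrogen-responsive genes (median 0.59, 0 [1] of 31 rose, adjusted p 2.29e-05) and fibroblasts and matrix (median 0.44, 0 [0] of 39 passed, adjusted p 1.03e-07). So were endothelium (median 0.35, 0 [0] of 19 passed, adjusted p 0.00201) and nerve and ganglion (median 0.90, 0 [0] of 27 passed, adjusted p 2.29e-05). Lower were unfolded protein response (median -0.63, 0 [3] of 27 fell, adjusted p 2.09e-04) and the products of the neighbouring gland, seminal vesicle products (median -2.06, 0 [4] of 8 fell, adjusted p 4.59e-04). The 6 lists had adjusted p = 0.0607 to 0.869 with an estimated correlation. The matrix gene Lum, the endothelial gene Ramp2 and the Schwann cell gene S100b stood at 1.75 ± 0.62, 0.69 ± 0.29 and 1.20 ± 0.57. Svs6 and Svs5 stood at -5.75 to -9.01 (SE 1.78 to 2.08, adjusted p 0.0883 to 0.194). The count was 11 genes (2 higher, 9 lower), 13 with slide as a block and 17 with only these groups. It was 6 higher and 6 lower with quantile scaling, 8 higher and 68 lower with normexp and 37 in the tissue fit. Within slides 1 to 4 the list medians (slide block in parentheses) were 0.14 to 0.92 (0.35 to 0.59) for the higher lists, -0.13 to -3.58 (-0.63 to -2.06) for the lower lists and -1.93, 3.58, 0.28 and 2.27 (0.90) for nerve and ganglion. The nerve and ganglion shift was 0.34, adjusted p = 0.0297 without EB 2. Calls numbered 8, 17, 7 or 12 when control 1, 2, 3 or 4 was left out, and the 7 named genes kept 5, 6, 5 or 6. Leaving out EB 1, 2, 3 or 4 gave 514, 8, 7 or 8, with 7, 5, 5 or 5 named.

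EB at PND 100 asked whether that exposure was visible in the adult. Genes of the adaptive immune system rose, led by the immunoglobulin joining chain Jchain (5.49 ± 0.90, adjusted p 0.00402) in 3 against 3 arrays. The B cell factor Spib, the B cell chemokine Cxcl13, the T cell inhibitor Vtcn1 and the helicase Ddx60 rose too (4.35 to 4.67, SE 0.81 to 1.12, adjusted p 0.0101 to 0.0352). Scart1 rose from below background, at least 16.9-fold (adjusted p 0.00809), and the bound for Sdr16c5 was at least 11.7-fold (adjusted p 0.148). Elmod1, Angptl1, Acbd7, Rn5-8s, Atp13a5 and Gucy2c fell (-2.55 to -4.28, SE 0.68 to 0.90, adjusted p 0.0047 to 0.0466). The immune lists lay higher together, T and NK cells (median 2.17, 9 [22] of 27 rose, adjusted p 3.27e-13) and B cells and plasma cells (median 2.27, 3 [10] of 19 rose, adjusted p 5.76e-06). The innate lists were myeloid cells (median 1.82, 12 [24] of 31 rose, adjusted p 2.21e-17) and inflammatory mediators (median 1.64, 4 [19] of 42 rose, adjusted p 1.77e-11). Higher too were antigen presentation (median 1.64, 7 [13] of 20 rose, adjusted p 1.43e-09) and interferon response (median 1.67, 3 [19] of 33 rose, adjusted p 8.12e-12). Outside the immune system fibroblasts and matrix (median 1.5, 6 [26] of 39 rose, adjusted p 2.05e-15), endothelium (median 1.31, 3 [11] of 19 rose, adjusted p 3.70e-07) and estrogen-responsive genes (median 0.57, 3 [6] of 31 rose, 1 [1] fell, adjusted p 0.00285) were higher. Lower were unfolded protein response (median -0.93, 3 [13] of 27 fell, adjusted p 9.74e-10) and seminal vesicle products (median -3.56, 0 [6] of 8 fell, adjusted p 1.03e-04). For these lists the result was adjusted p = 0.193 to 0.21 with an estimated correlation. Cd4 and Zap70 of T cells (1.85 to 3.19, SE 0.31 to 0.61, adjusted p 0.00403 to 0.0109) and Adgre1 and C1qb of macrophages (1.99 to 2.91, SE 0.41 to 0.55, adjusted p 0.0107 to 0.0186) rose. Cd74 and RT1-Bb of class II presentation (2.50 to 2.72, SE 0.51 to 0.62, adjusted p 0.0186 to 0.0266) and tumour necrosis factor (Tnf) and Ccl5 (2.37 to 3.49, SE 0.60 to 0.88, adjusted p 0.0365 to 0.0372) rose as well. Atf4 and Pdia3 fell (-1.03 to -1.56, SE 0.23 to 0.39, adjusted p 0.0254 to 0.0361). Pate4 and Svs5 were not well above background with EB, at least 55.0-fold (adjusted p 0.0618) and at least 26.9-fold (adjusted p 0.0909) lower, without passing.

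The seminal vesicle medians were -2.12, -5.72 and -4.56 on the EB arrays of PND 100 and -2.02, -2.13 and 3.21 on the controls. EB called 627 genes (423 higher, 204 lower), 1605 with slide as a block (1051 higher), 52 higher and 24 lower with normexp, 264 with no filter and, by limma on only these groups, 0 (4120). The B and plasma cell shift was 0.93, adjusted p = 6.02e-04 without EB 3. In the reduced fit the count was 47. On slides 1 and 2, which held both groups, list medians (slide block in parentheses) were 0.62 to 5.84 (0.65 to 2.63) for the higher lists and -0.89 to -8.35 (-1.04 to -3.31) for the lower lists. With control 1, 2 or 3 left out the count was 29, 170 or 50, and 4, 11 or 7 of the 22 named genes kept the call. With EB 1, 2 or 3 left out it was 2717, 408 or 7, with 21, 15 or 1 named.

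At PND 145 the EB effect covered immune lists again, with T and NK cells (median 0.84, 0 [1] of 27 rose, adjusted p 2.49e-04) and myeloid cells (median 0.84, 0 [0] of 31 passed, adjusted p 4.59e-06). Higher were also inflammatory mediators (median 1.09, 0 [0] of 42 passed, adjusted p 1.93e-06), antigen presentation (median 0.95, 0 [0] of 20 passed, adjusted p 6.18e-05) and interferon response (median 1.07, 0 [0] of 33 passed, adjusted p 2.01e-07). Of other tissues, fibroblasts and matrix (median 0.39, 1 [5] of 39 rose, adjusted p 1.31e-04) and basal and squamous epithelium (median 0.40, 1 [1] of 26 rose, adjusted p 0.0156) lay higher. So did nerve and ganglion (median 2.49, 0 [10] of 27 rose, adjusted p 2.24e-08) and skeletal muscle (median 2.16, 0 [0] of 18 passed, adjusted p 0.0182). Lower were unfolded protein response (median -0.51, 0 [2] of 27 fell, adjusted p 1.55e-05) and seminal vesicle products (median -4.06, 2 [5] of 8 fell, adjusted p 2.34e-06). The lists had adjusted p = 0.529 to 0.742 with an estimated correlation. The matrix protein periostin (Postn) rose (2.68 ± 0.54, adjusted p 0.0225) in 4 against 3 arrays, as did S100a14 (2.40 ± 0.55, adjusted p 0.0398) and the pseudogene Rps4x-ps1 (9.32 ± 2.19, adjusted p 0.0438). The lipoxygenase Alox12e, the glutathione transferase Mgst1, Fam171b and the glutamate receptor Gria4 rose too (2.46 to 2.74, SE 0.45 to 0.64, adjusted p 0.0169 to 0.0438). Svs1 and Svs5 fell (-6.24 to -8.11, SE 1.44 to 1.93, adjusted p 0.0398 to 0.0474). The genes with the largest falls otherwise belong to maturing sperm cells. The transition proteins Tnp1 and Tnp2 with Gsg1, Smcp and Oaz3 fell (-5.68 to -6.56, SE 1.21 to 1.47, adjusted p 0.0225 to 0.0398), and Crisp2 and Prm3 had bounds of at least 44.4-fold (adjusted p 0.0184) and at least 23.4-fold (adjusted p 0.0389). On the 3 controls, a list of 19 measured spermatid genes, set up after these values were seen, had means of -4.48, 1.36 and -5.92, and without control 2 0 of its 13 calls were left. Lipo1 and Sdr16c5 were well above background with EB only, at least 93.0-fold (adjusted p 0.0844) and at least 50.9-fold (adjusted p 0.0782).

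The skeletal muscle call of EB at PND 145 was lost with slide as a block (0.0889) and without control 3 (0.182), EB 2 (0.382) or EB 4 (0.0904). The basal and squamous call was lost without EB 2 (0.0812). The count was 133 genes (45 higher, 88 lower), 32 with slide as a block and 7 higher and 23 lower with normexp. It was 2 in the reduced fit, and by limma 0 (4131) on only these groups and 0 (1127) in the tissue fit. Slides 3 and 4 held both groups, with list medians (slide block) of 0.42 to 4.35 (0.33 to 2.12) for the higher lists and -0.55 to -6.39 (-0.45 to -4.30) for the lower lists. Leaving out control 1, 2 or 3 gave 72, 6 or 221 called genes, with 8, 0 or 13 of the 16 named. Without EB 1, 2, 3 or 4 it was 103, 63, 10 or 52, with 11, 3, 0 or 3 named.

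T+E alone at PND 100 asked what the adult implants did on their own. Cholesterol synthesis genes were higher, cholesterol and fatty acid synthesis (median 1.04, 1 [4] of 26 rose, adjusted p 2.18e-12), at adjusted p = 0.981 with an estimated correlation. Hmgcs1 stood at 2.33 ± 0.57. The ventral products, markers of 1 lobe, lay at 5.87 ± 0.21 with T+E and 2.54 ± 2.82 in controls (SD, n = 3). Hapln2, a hyaluronan link protein, rose (4.69 ± 0.76, adjusted p 0.00761) in 3 against 3 arrays, with Khdrbs2, Zbtb40, B4galt6, Akap14 and Raph1 (2.95 to 4.69, SE 0.58 to 0.83, adjusted p 0.00435 to 0.0493). Slc37a2, the synaptic scaffold Homer1, Elapor2 and Impa2 fell (-1.80 to -2.96, SE 0.39 to 0.60, adjusted p 0.025 to 0.0488). The bound for Slc5a8 was at least 38.7-fold (adjusted p 0.284) higher. The neuropeptide Vip and the epithelial factor Foxa2 had bounds of at least 9.15-fold (adjusted p 0.319) and at least 8.63-fold (adjusted p 0.152) lower. Higher were also fibroblasts and matrix (median 0.80, 0 [0] of 39 passed, adjusted p 1.15e-09) and endothelium (median 0.49, 0 [0] of 19 passed, adjusted p 0.00919). Lower was nerve and ganglion (median -1.16, 0 [0] of 27 passed, adjusted p 4.35e-04), and these lists had adjusted p = 0.981 with an estimated correlation. The nerve and ganglion call ended without control 3 (-0.62, adjusted p = 0.0876) and the endothelial call without control 1 (0.35, adjusted p = 0.0698). T+E called 45 genes (33 higher, 12 lower), 81 with slide as a block, 248 with only these groups, 22 higher and 2 lower with normexp, 15 in the ventral and 242 in the tissue fit. By limma in the reduced fit it was 0 (1504). Within slides 1, 2 and 3 the medians (slide block) were 0.01 to 1.91 (0.49 to 1.04) for the higher lists, -0.13 to -2.66 (-1.16) for the lower lists and 1.18, 1.19 and -0.10 (0.80) for fibroblasts and matrix. Without control 1, 2 or 3 there were 13, 0 (1682) or 3 calls, 3, 0 or 1 of them among the 10 named genes. Removing T+E 1, 2 or 3 gave 33, 9 or 31, with 5, 2 or 6 named.

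At PND 145 Hapln2 and Zbtb40 rose with T+E again (5.33 to 5.97, SE 0.58 to 0.76, adjusted p 4.83e-06 to 5.23e-05). Hepatocyte growth factor (Hgf) rose (6.15 ± 0.56, adjusted p 3.07e-07) in 3 against 3 arrays, with the calmegin gene Clgn, Saal1 and the mucin-type glycosyltransferase Gcnt3 (6.30 to 7.83, SE 1.25 to 1.52, adjusted p 0.00125 to 0.0495). Clca1, a goblet cell product, and the aldose reductase relative Akr1b7 rose from below background, at least 1883-fold (adjusted p 1.40e-04) and at least 60.3-fold (adjusted p 1.83e-09). Glt1d1, Fam171a2, Spata24 and Apc2 fell (-1.97 to -3.37, SE 0.41 to 0.69, adjusted p 0.0192 to 0.0383). So did the spermatid genes Prm1 and Hils1 (-4.92 to -5.80, SE 1.12 to 1.23, adjusted p 0.0264 to 0.0463), with bounds for Tnp1 and Smcp of at least 102-fold (adjusted p 0.0179) and at least 50.0-fold (adjusted p 0.0179). Without control 2 these 4 stood at -2.76 to -5.21 (adjusted p 0.169 to 0.315). Lists that lay higher were fibroblasts and matrix (median 1.01, 0 [0] of 39 passed, adjusted p 1.59e-15) and myeloid cells (median 1.03, 0 [0] of 31 passed, adjusted p 4.96e-12). Inflammatory ones were inflammatory mediators (median 1.03, 0 [0] of 42 passed, adjusted p 5.76e-09) and mast cells and eosinophils (median 1.15, 0 [3] of 13 rose, adjusted p 3.20e-05). Further higher lists were T and NK cells (median 0.64, 0 [1] of 27 rose, adjusted p 2.13e-04), antigen presentation (median 0.82, 0 [2] of 20 rose, adjusted p 2.41e-05) and estrogen-responsive genes (median 0.53, 0 [3] of 31 rose, adjusted p 6.02e-04). Lower were cholesterol and fatty acid synthesis (median -0.75, 0 [0] of 26 passed, adjusted p 4.30e-06) and seminal vesicle products (median -3.32, 0 [1] of 8 fell, adjusted p 0.00486). Ventral products lay at 1.60 ± 0.83 with T+E and 4.48 ± 1.55 in controls (SD, n = 3). These lists had adjusted p = 0.348 to 0.482 with an estimated correlation.

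**Figure D2:**
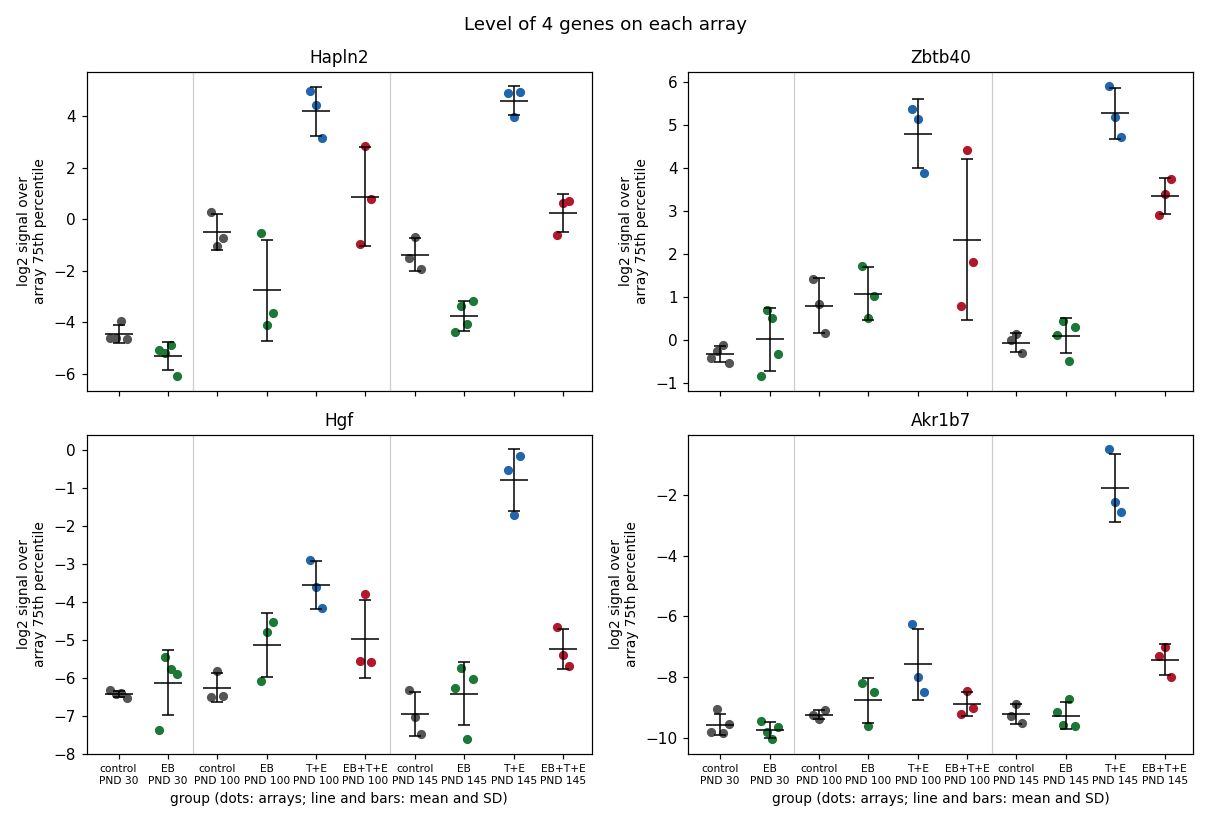
Levels of Hapln2, Zbtb40, Hgf and Akr1b7 on each array (log2 signal over the array's 75th percentile), by group, with the group mean and SD. With T+E at PND 145 Hgf lay 6.15 ± 0.56 above control on the log2 scale.

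With T+E at PND 145 the T and NK cell list stood at 0.28, adjusted p = 0.0615 without T+E 2. Seminal vesicle products stood at -1.47, adjusted p = 0.246 without control 2 and lost their call with the filter of 17 arrays (0.126). In all 89 genes changed (67 higher, 22 lower), 77 with slide as a block and 23 with only these groups. The count was 58 higher and 4 lower with normexp and 53 in the reduced fit. List medians within slides 1, 3 and 4 (slide block) were 0.10 to 2.62 (0.64 to 1.15) for the higher lists, -0.45 to -7.32 (-0.75 to -3.32) for the lower lists and 0.29, 1.16 and -0.02 (0.53) for estrogen-responsive genes. Calls numbered 61, 53 or 177 (66 higher) when control 1, 2 or 3 was left out, and the 16 named genes kept 12, 6 or 13. Leaving out T+E 1, 2 or 3 gave 56, 66 or 57, with 9, 8 or 6 named.

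EB+T+E at PND 100 asked how the combined exposure differed from control. The calgranulin gene S100a9 rose (7.38 ± 1.53, adjusted p 0.00327) in 3 against 3 arrays, and its partner S100a8 rose from below background, at least 84.0-fold (adjusted p 0.00289). Cxcl2, Stfa2l2, Sirpd, the lectin Clec4a2 and the interleukin decoy receptor Il1r2 rose (5.15 to 6.91, SE 0.82 to 1.86, adjusted p 5.89e-04 to 0.0162), and the pseudogene Rps4x-ps1 at least 77.0-fold (adjusted p 0.0412). The receptor Gprc6a, Cdh7, Atp13a4, Gpc5, Elmod1 and the metallothionein Mt3 fell (-4.55 to -6.23, SE 0.73 to 1.25, adjusted p 7.06e-04 to 0.00392). Pate4 fell at least 46.6-fold (adjusted p 0.0332), a call lost in 9 of 17 settings (-1.69 in the tissue fit). The bound for Dnase2b, at least 56.3-fold (adjusted p 0.0869) lower, did not pass, and the tissue fit put it at 0.20. Dividing-cell genes rose as proliferation (median 2.12, 35 [40] of 44 rose, adjusted p 1.29e-26). So did myeloid cells (median 2.53, 24 [29] of 31 rose, adjusted p 6.80e-25) and inflammatory mediators (median 2.33, 20 [28] of 42 rose, adjusted p 8.42e-16). Higher too were T and NK cells (median 1.49, 5 [6] of 27 rose, adjusted p 9.77e-07) and antigen presentation (median 1.24, 7 [9] of 20 rose, adjusted p 3.55e-07). Outside the immune system fibroblasts and matrix (median 1.46, 20 [25] of 39 rose, 1 [1] fell, adjusted p 3.44e-13), endothelium (median 1.51, 9 [15] of 19 rose, adjusted p 2.34e-08) and estrogen-responsive genes (median 0.52, 5 [5] of 31 rose, 1 [2] fell, adjusted p 0.0188) lay higher. Lower were luminal epithelium (median -1.36, 0 [1] of 30 rose, 9 [18] fell, adjusted p 1.48e-06) and seminal vesicle products (median -3.74, 5 [5] of 8 fell, adjusted p 2.93e-04). The lists had adjusted p = 0.195 to 0.392 with an estimated correlation. Uhrf1, Bub1 and Plk1 (2.71 to 2.99, SE 0.45 to 0.52, adjusted p 8.01e-04 to 0.00203) rose. Interleukin 1 beta (Il1b) and Nos2 (3.62 to 5.04, SE 0.72 to 0.99, adjusted p 0.00239 to 0.00254) and Cd4 and Icos (2.04 to 3.72, SE 0.31 to 0.87, adjusted p 5.89e-04 to 0.00705) rose likewise. The epithelial factor Foxa1 and the adhesion molecule Epcam fell (-1.65 to -2.33, SE 0.43 to 0.45, adjusted p 0.00213 to 0.0145), and so did Svs4 and Spink8 (-2.16 to -2.31, SE 0.43 to 0.58, adjusted p 0.00177 to 0.0159).

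With EB+T+E at PND 100 the luminal medians were -1.03, 1.79 and 1.51, against 1.71, 1.54 and 1.56 in controls, and without EB+T+E 1 the shift was -0.33, adjusted p = 0.0332. The call of estrogen-responsive genes was lost without EB+T+E 2 (0.44, adjusted p = 0.058). The combination called 2943 genes (1262 higher, 1681 lower), 3382 with slide as a block and, by limma on only these groups, 0 (3649). The count was 1635 in the reduced fit. More were higher than lower with normexp (915 against 853), array weights (2486 and 2338) and the tissue fit (351 and 205). Both groups shared slides 1 and 2, where list medians (slide block) were 0.18 to 3.39 (0.51 to 2.75) for the higher lists and -0.55 to -8.71 (-1.50 to -3.14) for the lower lists. With control 1, 2 or 3 left out the count was 1352, 1653 or 1737, and 26, 27 or 26 of the 29 named genes kept the call. With EB+T+E 1, 2 or 3 left out it was 706, 3278 or 5752, with 20, 27 or 28 named.

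At PND 145 the combined exposure gave the largest count against control, 8252 genes (3434 higher, 4818 lower). Plasma cell and B cell genes rose, Jchain (9.30 ± 0.90, adjusted p 1.76e-07) in 3 against 3 arrays and the immunoglobulin segment Igkv28 (9.16 ± 1.42, adjusted p 3.38e-05). The Ly6 family genes Lypd8l2, Ly6al and Ly6i rose (8.06 to 9.41, SE 1.30 to 1.91, adjusted p 5.40e-05 to 5.79e-04), and Clca1 and Cxcl2 rose from below background, at least 5708-fold (adjusted p 2.65e-06) and at least 1135-fold (adjusted p 1.32e-04). Lymphocyte lists were B cells and plasma cells (median 5.00, 15 [15] of 19 rose, 1 [1] fell, adjusted p 1.09e-10) and T and NK cells (median 3.93, 24 [24] of 27 rose, 0 [1] fell, adjusted p 6.95e-19). Other immune lists were myeloid cells (median 3.72, 29 [29] of 31 rose, adjusted p 2.70e-24) and inflammatory mediators (median 4.23, 38 [38] of 42 rose, adjusted p 5.89e-21). Higher were also antigen presentation (median 3.26, 18 [19] of 20 rose, adjusted p 1.76e-14) and interferon response (median 3.84, 28 [29] of 33 rose, 0 [1] fell, adjusted p 7.36e-20). Of the tissue lists, fibroblasts and matrix (median 1.95, 30 [34] of 39 rose, adjusted p 1.77e-14) and endothelium (median 1.62, 14 [14] of 19 rose, 0 [1] fell, adjusted p 5.31e-06) lay higher. The same held for proliferation (median 1.20, 17 [17] of 44 rose, adjusted p 4.58e-06), estrogen-responsive genes (median 0.71, 12 [14] of 31 rose, 2 [3] fell, adjusted p 0.0025) and nerve and ganglion (median 2.72, 12 [13] of 27 rose, adjusted p 4.58e-06). Lower were unfolded protein response (median -1.18, 1 [1] of 27 rose, 17 [18] fell, adjusted p 1.42e-04) and seminal vesicle products (median -2.90, 3 [5] of 8 fell, adjusted p 0.0391). The lists had adjusted p = 0.075 to 0.582 with an estimated correlation. Mzb1 and Tnfrsf17 (6.98 to 7.55, SE 0.87 to 0.95, adjusted p 3.86e-06 to 4.01e-06) and Icos, the killer cell protein Prf1 and Cd4 (2.74 to 7.78, SE 0.31 to 0.87, adjusted p 1.17e-06 to 1.40e-06) rose. Siglec1, C1qb and Adgre1 of macrophages rose (3.54 to 6.14, SE 0.41 to 0.69, adjusted p 1.17e-06 to 1.89e-06), and so did the chemokines Ccl3, Cxcl13, Ccl5 and Cxcl9 (4.07 to 7.86, SE 0.55 to 1.12, adjusted p 1.89e-06 to 1.38e-05). The chaperones Hsp90b1 and Pdia4 (-1.56 to -1.59, SE 0.28 to 0.31, adjusted p 1.57e-04 to 4.16e-04) and the genes Mfsd2a and Havcr1 (-5.19 to -5.39, SE 1.17 to 1.49, adjusted p 0.00109 to 0.00919) fell. So did Spink8 and Svs4 (-1.47 to -2.37, SE 0.43 to 0.58, adjusted p 0.0029 to 0.00997) and the spermatid genes Tnp1, Oaz3, Tnp2 and Smcp (-5.85 to -6.77, SE 1.29 to 1.51, adjusted p 9.19e-04 to 0.00188), the 4 at -3.61 to -4.45 (adjusted p 0.0132 to 0.0282) without control 2. In the tissue fit 0 of these 4 passed (adjusted p 0.0534 to 0.091). Crisp2 and Tcp10b fell at least 53.6-fold (adjusted p 0.0012) and at least 33.5-fold (adjusted p 0.0159), and without control 2 stood at -4.25, adjusted p = 0.0185 and -3.34, adjusted p = 0.157.

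Seminal vesicle products lost their call with EB+T+E at PND 145 with slide as a block (0.0574), normexp (0.0692), the filter of 17 arrays (0.0858) or only these groups (0.0519). It was also lost without control 2 (0.195) or EB+T+E 3 (0.214). On the EB+T+E arrays the B and plasma cell medians were -1.44, -1.35 and -3.17 and the seminal vesicle medians -0.79, -0.52 and -6.80. With slide as a block 7768 genes were called and with only these groups 7772. The tissue fit left 2907, 1683 higher and 1224 lower. Quantile scaling put the median of all genes at -0.13 and normexp at -0.31. Within slides 3 and 4 (slide block in parentheses) the list medians were 0.16 to 5.57 (0.71 to 4.66) for the higher lists and -0.84 to -4.86 (-1.17 to -2.98) for the lower lists. Leaving out control 2 gave 5782 called genes, with 34 of the 36 named. Without EB+T+E 1 or 3 it was 5201 or 8559, with 34 or 35 named.

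EB+T+E against T+E asked what the neonatal estrogen added to the adult implants. At PND 100 Cxcl2, S100a9 and Stfa2l2 rose (5.93 to 7.19, SE 1.36 to 1.86, adjusted p 0.0126 to 0.0301). S100a8 and Vip rose from below background, at least 75.1-fold (adjusted p 0.0154) and at least 86.5-fold (adjusted p 0.00841). Khdrbs2, Wfdc13 and Elmod1 fell (-3.74 to -4.48, SE 0.73 to 1.05, adjusted p 0.00652 to 0.0417), with bounds of at least 14.3-fold (adjusted p 0.00568) for the vomeronasal receptor Vom2r4 and, without passing, at least 89.5-fold (adjusted p 0.0956) for Dnase2b. Higher lists were proliferation (median 2.17, 29 [40] of 44 rose, adjusted p 1.24e-31) and inflammatory mediators (median 2.65, 16 [31] of 42 rose, adjusted p 6.69e-20). Higher were also myeloid cells (median 2.25, 22 [26] of 31 rose, adjusted p 2.65e-25), T and NK cells (median 1.25, 2 [3] of 27 rose, adjusted p 3.62e-05) and nerve and ganglion (median 2.00, 3 [4] of 27 rose, adjusted p 4.26e-07). Lower were luminal epithelium (median -1.25, 2 [3] of 30 fell, adjusted p 2.55e-06) and cholesterol and fatty acid synthesis (median -1.03, 1 [1] of 26 fell, adjusted p 8.86e-06). The 7 lists had adjusted p = 0.114 to 0.468 with an estimated correlation. Mcm6 and Tpx2 (2.07 to 2.50, SE 0.32 to 0.48, adjusted p 0.00404 to 0.00761) and Fcgr2b and Cd163 (3.57 to 3.72, SE 0.65 to 0.67, adjusted p 0.00568 to 0.00652) rose. Without EB+T+E 1 the luminal shift was -0.25, adjusted p = 0.11 and the cholesterol shift -0.51, adjusted p = 3.33e-04. The count of 935 genes (621 higher, 314 lower) was 1588 with slide as a block. By limma it was 0 (2165) on only these groups and 0 (3313) in the tissue fit. Slides 1 and 2 gave list medians (slide block) of 1.29 to 3.65 (1.47 to 2.82) for the higher lists and -0.39 to -3.28 (-1.21 to -1.34) for the lower lists. Without EB+T+E 1, 2 or 3 there were 8, 1518 (601 higher) or 5562 (2442 higher) calls, 2, 11 or 13 of them among the 13 named genes. Removing T+E 1, 2 or 3 gave 14, 302 or 800, with 1, 10 or 10 named.

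At PND 145 EB+T+E exceeded T+E in lymphoid genes, with Jchain, Spib and the lymphocyte chemokine Ccl19 higher (7.37 to 8.02, SE 0.90 to 1.12, adjusted p 3.71e-06 to 6.71e-05). Igkv28 rose from below background, at least 227-fold (adjusted p 5.79e-05). The milk protein gene Csn2, Akr1b7 and the salivary protein gene Stath fell (-5.20 to -6.42, SE 0.53 to 1.79, adjusted p 1.82e-07 to 0.0386). Spx and Bmp3 fell to levels not well above background, at least 49.1-fold (adjusted p 2.15e-05) and at least 8.53-fold (adjusted p 0.0162). Higher lists were B cells and plasma cells (median 4.68, 14 [14] of 19 rose, 0 [1] fell, adjusted p 1.74e-12) and T and NK cells (median 3.82, 23 [24] of 27 rose, 0 [1] fell, adjusted p 4.28e-19). Others were interferon response (median 3.44, 28 [29] of 33 rose, adjusted p 3.38e-21) and inflammatory mediators (median 3.06, 28 [34] of 42 rose, adjusted p 2.34e-17). Higher too were myeloid cells (median 2.60, 28 [28] of 31 rose, adjusted p 6.93e-21) and proliferation (median 1.59, 25 [34] of 44 rose, 0 [1] fell, adjusted p 5.08e-14). Lower was unfolded protein response (median -1.15, 15 [19] of 27 fell, adjusted p 1.19e-06), and the 7 lists had adjusted p = 0.0915 to 0.45 with an estimated correlation. Tnfrsf17 and Mzb1 (6.76 to 7.44, SE 0.87 to 0.95, adjusted p 1.97e-05 to 2.05e-05) rose. Hyou1 and Pdia4 fell (-1.38 to -1.60, SE 0.28 to 0.33, adjusted p 0.0012 to 0.00126). There were 4992 genes (2262 higher, 2730 lower), 4638 with slide as a block. More were higher than lower in the tissue fit (1359 against 1124), with only these groups (2005 and 1812) and with quantile scaling (2249 and 2233). On slides 3 and 4 list medians (slide block) were 1.25 to 5.02 (1.60 to 4.40) for the higher lists and -0.87 to -0.95 (-1.13) for the lower lists. Calls numbered 2756 (1391 higher) or 2985 when EB+T+E 1 or 2 was left out, and the 14 named genes kept 11 or 12. Leaving out T+E 1 or 3 gave 3159 (1599 higher) or 2346 (1319 higher), with 11 each named.

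EB+T+E against EB asked what the implants added to neonatal estrogen. At PND 100 the macrophage receptor Cd209f, the troponin Tnnc1 and Cenpu rose (2.95 to 3.44, SE 0.58 to 0.80, adjusted p 0.0137 to 0.0334). Kcng1, the synaptic gene Rims1 and Veph1 fell (-3.62 to -4.36, SE 0.57 to 0.81, adjusted p 0.00428 to 0.023), and Kctd8 fell at least 5.63-fold (adjusted p 0.00585). Bounds that did not pass were at least 3.14-fold (adjusted p 0.0726) higher for Krt76, at least 2.19-fold (adjusted p 0.171) higher for Sox11 and at least 5.99-fold (adjusted p 0.0702) lower for Tacr2. Higher were proliferation (median 1.45, 3 [32] of 44 rose, adjusted p 4.45e-25) and myeloid cells (median 0.67, 1 [1] of 31 rose, adjusted p 2.90e-05). Lower were developmental signalling (median -0.95, 4 [12] of 41 fell, adjusted p 2.05e-05), T and NK cells (median -0.87, 0 [0] of 27 passed, adjusted p 0.042) and B cells and plasma cells (median -1.24, 0 [1] of 19 fell, adjusted p 0.0157). The 5 lists had adjusted p = 0.228 to 0.817 with an estimated correlation. Uhrf1, Cdkn3 and Mcm6 rose (1.23 to 2.63, SE 0.32 to 0.54, adjusted p 0.00585 to 0.0439), and Fgfr2, Bmp7 and Sox9 fell (-1.60 to -1.90, SE 0.35 to 0.46, adjusted p 0.0102 to 0.0343). Without EB 3 the T and NK shift was 0.01, adjusted p = 0.527 and the B and plasma cell shift -0.18, adjusted p = 0.925. The T and NK call was also lost with quantile scaling (0.0635), the filter of 17 arrays (0.0905), only these groups (0.0749), and without EB 2 (0.0991), EB+T+E 2 (0.0999) or EB+T+E 3 (0.583). The B and plasma cell call was lost with that filter (0.541), only these groups (0.112) or without EB+T+E 3 (0.14). The myeloid call was lost without EB 1 (0.847) or EB+T+E 1 (0.304). Of 400 genes 166 were higher and 234 lower, against 123 higher and 64 lower with normexp, 201 and 170 in the authors' deposited table, 173 and 113 with array weights and 135 and 114 in the ventral fit. There were 354 with slide as a block, 1286 in the tissue fit and, by limma on only these groups, 0 (988). Medians on slides 1, 2 and 4 (slide block) were 0.59 to 3.01 (1.45) for the higher lists, -0.39 to -0.95 (-0.95) for the lower lists, 1.14, -0.10 and 1.22 (0.67) for myeloid cells, -0.73, -2.14 and 0.60 (-0.87) for T and NK cells and -0.22, -2.51 and 0.40 (-1.24) for B cells and plasma cells. With EB 1, 2 or 3 left out the count was 700, 140 or 22, and 10, 6 or 3 of the 13 named genes kept the call. With EB+T+E 1, 2 or 3 left out it was 47, 1180 or 1128, with 4, 13 or 12 named.

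At PND 145 EB+T+E exceeded EB in Clca1, Ly6al and Igkv28 (8.34 to 10.48, SE 1.33 to 1.51, adjusted p 4.36e-05 to 1.95e-04), in 3 against 4 arrays. The B cell receptor chain Cd79b and the plasma cell receptor Tnfrsf17 rose from below background, at least 68.7-fold (adjusted p 7.52e-05) and at least 60.3-fold (adjusted p 6.23e-06). Vstm2a, Scgb1d4 and Sdr16c5 fell (-5.09 to -6.41, SE 1.36 to 2.06, adjusted p 0.00147 to 0.0356), as did Lipo1 and the connexin Gjb6, at least 108-fold (adjusted p 0.00508) and at least 14-fold (adjusted p 0.001). Scgb1d4 is 1 of 4 ventral prostate products, whose mean level was 5.61 ± 0.70 (SD, n = 4) with EB and 1.12 ± 3.82 (SD, n = 3) with EB+T+E. Higher lists were B cells and plasma cells (median 4.41, 15 [15] of 19 rose, adjusted p 1.71e-13) and T and NK cells (median 3.66, 24 [24] of 27 rose, adjusted p 5.60e-20). Also higher were myeloid cells (median 2.83, 28 [28] of 31 rose, adjusted p 7.31e-25) and inflammatory mediators (median 3.03, 33 [36] of 42 rose, adjusted p 1.00e-19). Higher too were proliferation (median 1.45, 26 [28] of 44 rose, adjusted p 2.76e-12) and fibroblasts and matrix (median 1.39, 18 [22] of 39 rose, adjusted p 4.64e-12). Lower was smooth muscle (median -1.06, 11 [11] of 26 fell, adjusted p 1.43e-04), and the 7 lists had adjusted p = 0.0639 to 0.51 with an estimated correlation. Jchain and Mzb1 (6.65 to 7.59, SE 0.82 to 0.84, adjusted p 1.73e-06 to 6.72e-06) and Cd4 and Gzmk (2.72 to 3.66, SE 0.29 to 0.50, adjusted p 1.22e-06 to 2.58e-05) rose. Kcnmb1 and Myh11 fell (-1.60 to -1.83, SE 0.40 to 0.42, adjusted p 0.00204 to 0.00786). The count was 5350 (2470 higher, 2880 lower), 4904 with slide as a block. More were higher than lower in the ventral fit (1412 against 1198), with quantile scaling (2695 and 2215), the authors' deposited table (2579 and 2132) and only these groups (2151 and 1408). Slides 2, 3 and 4 gave medians (slide block) of 1.03 to 5.61 (1.37 to 4.21) for the higher lists and -0.37, -2.58 and 0.03 (-1.14) for smooth muscle. Leaving out EB 1, 3 or 4 gave 3682 (1927 higher), 4233 (2164 higher) or 4482 called genes, with 14, 15 or 15 of the 16 named. Without EB+T+E 1 or 2 it was 2781 (1559 higher) or 3000 (1637 higher), with 14 or 13 named.

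The interaction asked whether EB+T+E differed from the sum of the EB and T+E effects. At PND 100 limma called 0 genes (2015), 0 (1202) with only these groups and 14 in the tissue fit. Camera called 15 lists, of which 3 are described. Above the sum lay proliferation (median 1.20, 0 [5] of 44 higher, adjusted p 6.69e-17) and nerve and ganglion (median 2.92, 0 [2] of 27 higher, adjusted p 2.06e-08). Below it lay developmental signalling (median -0.75, 0 [0] of 41 passed, adjusted p 2.27e-04), and the 3 lists had adjusted p = 0.427 to 0.79 with an estimated correlation. Slides 1 and 2, which held all 4 groups, gave medians (slide block) of 0.77 to 6.28 (1.20 to 2.92) for the higher lists and -0.75 to -1.03 (-0.75) for the lower lists. Without EB+T+E 3 the developmental signalling shift was -0.70, adjusted p = 0.109. Without EB 1 or 2 there were 1 or 3 calls. Removing EB+T+E 3 gave 351.

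At PND 145 the B cell genes lay above the sum of both effects, with B cells and plasma cells (median 4.24, 7 [14] of 19 higher, adjusted p 1.88e-15). This list kept its call with an estimated correlation (adjusted p = 0.0334). Jchain, the B cell coactivator Pou2af1, Tnfrsf17, Mzb1 and Fcrla were higher (3.78 to 7.20, SE 0.71 to 1.30, adjusted p 0.00825 to 0.0212). The spermatid gene Gsg1 was higher too (8.78 ± 2.16, adjusted p 0.0491), but its call was lost in 19 of 25 settings (6.46, adjusted p = 0.152 without control 2). Hgf, Taar1 and Lrrn3 lay below the sum (-4.98 to -5.59, SE 0.77 to 1.18, adjusted p 0.00182 to 0.0245). Higher were also T and NK cells (median 2.72, 0 [20] of 27 higher, adjusted p 3.84e-17) and proliferation (median 1.89, 3 [28] of 44 higher, adjusted p 5.38e-23). Another was interferon response (median 2.12, 2 [11] of 33 higher, adjusted p 1.62e-15), and these 3 lists had adjusted p = 0.161 with an estimated correlation. All 4 groups shared slides 3 and 4, with medians (slide block) of 1.27 to 5.31 (2.00 to 4.14) for the higher lists. The count was 180 genes (149 higher, 31 lower), 154 with slide as a block and 278 with only these groups. It was 56 in the reduced fit and 93 in the tissue fit. Calls numbered 92 or 87 when control 1 or 2 was left out, and the 9 named genes kept 5 or 8. Leaving out EB 1, 2, 3 or 4 gave 104, 103, 147 or 116, with 8, 7, 8 or 8 named. With EB+T+E 1, 2 or 3 left out it was 55, 44 or 665, with 7, 4 or 9 named. Without T+E 1 or 3 it was 52 or 65, with 4 or 6 named.

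Effects were then compared between ages. The EB effect differed between PND 100 and PND 30 for 5 genes, all higher, 19 with slide as a block, 3 in the ventral and 10 in the tissue fit and 0 (2000) by limma on only these groups. Among the 5 was the T cell adaptor Sh2d2a (4.81, adjusted p 0.0277), named after its values were seen. Lists that differed were T and NK cells (median 2.63, 0 [20] of 27 higher, adjusted p 5.99e-18) and antigen presentation (median 1.87, 0 [14] of 20 higher, adjusted p 1.05e-14), at adjusted p = 0.17 with an estimated correlation. Within slides 1 and 2 the medians (slide block) were 2.61 to 4.58 (2.06 to 2.98) for the higher lists. With control 1 of PND 30 left out the count was 0 (1832). Removing control 1 or 2 of PND 100 gave 3 or 0 (2147). Leaving out EB 1 or 2 of PND 100 gave 431 or 22. With EB 2 or 4 of PND 30 left out it was 3 each. Between PND 145 and PND 100 limma called 0 genes for the EB effect (1004) and 1 in the tissue fit. Leaving out control 1 of PND 145 gave 1 called gene. Without EB 1 or 2 of PND 100 it was 2 or 4. There proliferation (median -1.06, 0 [0] of 44 passed, adjusted p 3.56e-10) lay lower and nerve and ganglion (median 2.84, 0 [0] of 27 passed, adjusted p 7.92e-11) higher, at adjusted p = 0.549 with an estimated correlation. No slide held all 4 groups, and with slide as a block the medians were -1.41 and 2.33.

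The T+E effect differed between PND 145 and PND 100 for 6 genes (3 higher, 3 lower), with Tnfaip8l3 higher (3.47 ± 0.63, adjusted p 0.0467). The count was 21 with slide as a block, 1 higher and 0 lower with normexp, 1 in the ventral and 29 in the tissue fit. By limma it was 0 (2150) on only these groups and 0 (778) with the filter of 17 arrays. Lower at PND 145 was cholesterol and fatty acid synthesis (median -1.71, 1 [13] of 26 lower, adjusted p 1.54e-23), at adjusted p = 0.324 with an estimated correlation, beside the ventral products given above for both ages. The list medians on slides 1 and 3 (slide block) were -1.25 to -2.46 (-1.71) for the lower lists. Without control 1, 2 or 3 of PND 100 there was 1 call each. Removing control 1, 2 or 3 of PND 145 gave 12, 1 or 1. Leaving out T+E 1, 2 or 3 of PND 100 gave 3, 1 or 1. With T+E 1 or 2 of PND 145 left out it was 1 or 4. The 1 named gene was called in 0 of these fits.

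The EB+T+E effect was larger at PND 145 than at PND 100 in B cell genes, with B cells and plasma cells (median 4.10, 5 [13] of 19 higher, adjusted p 3.19e-14). This list kept its call with an estimated correlation (adjusted p = 0.0458). Mzb1, Jchain and Tnfrsf17 were higher (6.38 to 6.97, SE 1.23 to 1.34, adjusted p 0.0121 to 0.0336), and so were the steroid-synthesis enzyme Cyp17a1 and Tnfrsf14 (4.58 to 7.43, SE 1.00 to 1.43, adjusted p 0.0199 to 0.0403). Tmem52, Coq8a and Trim37 were lower (-1.83 to -4.35, SE 0.41 to 0.94, adjusted p 0.0263 to 0.046). Higher were also T and NK cells (median 2.97, 3 [19] of 27 higher, adjusted p 7.95e-18) and interferon response (median 2.31, 0 [20] of 33 higher, adjusted p 7.95e-18), at adjusted p = 0.135 with an estimated correlation. No slide held all 4 groups, and the medians of the 3 lists with slide as a block were 3.72, 2.72 and 2.11. The count was 76 genes (64 higher, 12 lower), 33 with slide as a block, 68 with only these groups and 57 higher and 1 lower with normexp. It was 7 in the ventral and 44 in the tissue fit, 2 with the filter of 17 arrays and 9 in the reduced fit. Ventral products lay at 5.48 ± 0.96 and 1.12 ± 3.82 (SD, n = 3) with EB+T+E at PND 100 and PND 145. Calls numbered 24, 22 or 21 when control 1, 2 or 3 of PND 100 was left out, and the 8 named genes kept 3, 2 or 2. Without control 1, 2 or 3 of PND 145 it was 34, 22 or 103 (48 higher), with 5, 2 or 6 named. Removing EB+T+E 1, 2 or 3 of PND 100 gave 17, 247 or 46, with 1, 8 or 3 named. Leaving out EB+T+E 1, 2 or 3 of PND 145 gave 16, 12 or 289, with 0, 0 or 8 named.

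Calls shared between PND 100 and PND 145 were counted, with different controls at each age. EB shared 15 higher genes (0.815 by chance) and 16 lower genes (0.769), and its log2 ratios correlated across genes at 0.519. T+E shared 10 higher (0.0947 by chance) and 2 lower genes (0.0113), with r = 0.141. EB+T+E shared 953 higher (186 by chance) and 1166 lower (347), with r = 0.655. Genes are not independent replicates, so these correlations carry no p-value. Opposite calls numbered 0, 0 and 4.

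Of the hormone receptors, against controls Esr1 lay between -1.10 and 1.19 (smallest adjusted p = 0.127) and Esr2 between -0.93 and 0.08. Of these 2, 0 passed limma's test against controls. The progesterone receptor Pgr rose with EB+T+E at PND 145 (2.35 ± 0.69, adjusted p 0.0105), at least 2.3-fold, a call lost with normexp (0.21, adjusted p = 0.49), in the tissue fit (adjusted p = 0.159) and without EB+T+E 1 (adjusted p = 0.0566). Esr1 fell against T+E in the EB+T+E group of PND 145 (-1.36 ± 0.47, adjusted p 0.0423), a call lost in 8 of 18 settings (adjusted p up to 0.184).

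Lists without a call against control in any of the 7 comparisons are given as the range of their medians with the smallest adjusted p. Prostate secretory products (-1.09 to 0.51, smallest adjusted p 0.275) had Tgm4 and Msmb as members with the highest levels. Androgen-responsive genes (-0.38 to -0.05, smallest adjusted p 0.182) had Tpd52 and Spcs3, and steroid receptors and steroid metabolism (-0.20 to 0.29, smallest adjusted p 0.229) Hsd17b11 and Hsd17b10. For urothelium (-1.79 to 1.33, smallest adjusted p 0.135) these were Upk1a and Upk1b. DNA methylation and neonatal estrogen imprint (-0.22 to 0.06, smallest adjusted p 0.414) had Pde4d and Mbd2, and oxidative stress and xenobiotic metabolism (0.01 to 0.36, smallest adjusted p 0.069) Mt2A and Prdx6. Adipocytes (-0.85 to 1.12, smallest adjusted p 0.0245) were called with EB at PND 100 alone, at -0.85 (adjusted p = 0.614 with an estimated correlation), with Cfd and Lpl at the highest levels. That call was lost with slide as a block (0.0772), the filter of 17 arrays (0.236) and without control 3 (0.635), EB 1 (0.118) or EB 2 (0.051). Single members did change with EB+T+E at PND 145. The secretory genes Msmb and Pbsn (-1.09 to -1.36, SE 0.26 to 0.36, adjusted p 0.00276 to 0.005) and the uroplakin Upk1a (-4.07 ± 0.51, adjusted p 3.86e-06) fell, and Maf rose (2.3 ± 0.41, adjusted p 1.35e-04). In mast cells and eosinophils the median there was -0.004 and the mean 0.97, which differ in sign.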

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

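The tests of the spermatid array, of slides and other tissue for the immune lists and of the lobes were chosen only after the results were seen. The seminal vesicle correlation and ventral slide share use a list and a pattern seen there. Splits of the arrays were set out beforehand.

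Dixon's test at the 95% level was run on 132 sets of 4 values, of which 7 had an array far from the others, and chance marks about 1 in 20 sets. The marked values, all at PND 30, were 0.365 for antigen presentation on control 1 (others -0.639 to -0.511) and -2.082 for endothelium on control 1 (others -1.847 to -1.801). Others were -3.39 for Lum on control 2 (others -0.678 to -0.362) and -7.525 for Svs5 on control 4 (others -2.404 to -1.733). Others were -5.224 for adipocytes on EB 1 (others -3.891 to -3.77) and -3.891 for Best4 on EB 1 (others -4.931 to -4.78). Others were -5.987 for Btg4 on EB 1 (others -9.005 to -8.679).

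Limma's test of the difference called 180 genes in the interaction at PND 145 and 76 for EB+T+E between PND 145 and PND 100. Of 100 splits 7 and 12 called as many, but these mixed all groups and cannot judge chance. It called 5 for EB between PND 100 and PND 30 and 6 for T+E between PND 145 and PND 100, but 0 (2000 and 2150 at an unadjusted p under 0.05) with only these groups fitted.

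Immune lists were higher with EB+T+E than control at PND 145. A difference between slides is argued against by the lowest within-slide T and NK cell median, 3.37. A lower share of the main cell type would raise all other cell types alike, but the T and NK cell median exceeded that of smooth muscle by 4.76. Lymphoid tissue taken with the prostate remains open. The lowest treated array lay 3.26 above the highest control array in the T and NK cell list and 4.96 in the B and plasma cell list, which such tissue in every sample could also give. An inflammatory response to the hormones may account for the shift, which was not tested.

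Spermatid transcripts were lower with EB than control at PND 145, by a median of -5.25. Without control 2 of that age the median was -3.06 with 0 calls left of 13, so 1 array decides the calls and this explanation stays open. RNA of the reproductive tract could have entered with seminal vesicle tissue. Over 25 adult arrays the deviations of both lists correlated at r = 0.447 (permutation p = 0.0266) and Spearman's rho = 0.292 (permutation p = 0.157), with r = 0.31 without the 2 farthest arrays, which leaves it open. No biological explanation was tested.

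Ventral prostate products differed between arrays of 1 group. Different shares of the lobes in the samples are a candidate explanation, since the 4 products deviated together with a lowest pairwise r of 0.788 over 33 arrays. A change of secretion as a whole is argued against, because the median within-group SD of the dorsolateral products Pbsn, Msmb and Tgm4 was 0.179 times that of the ventral ones. That of Tgm4 (0.94) lay near that of the ventral Scgb2a1 (1.03). Slide explained 0.165 of the variance (permutation p = 0.288), below the share set out for a slide effect.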

How the results depend on the processing

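The covariates for ventral products and other tissues and the fit without 2 control arrays were chosen after seeing the data, and the other alternatives were planned. Comparisons are named by treatment and age, against control unless another group is named. Counts are of genes called by limma, with the count at an unadjusted p under 0.05 in parentheses beside each 0. Of the values of named genes, 2 reversed under an alternative, Svs5 with EB at PND 100 (0.019) and Dnase2b with EB+T+E at PND 100 (0.20), both with the other tissue covariates. Camera's direction turned for 2 list shifts of EB+T+E against EB at PND 100 without EB 3. When single arrays were left out the T and NK cell median ranged from -1.84 to 0.011 and that of B and plasma cells from -2.44 to -0.18, which kept its sign. Of 813 list medians with 1 array left out, 67 moved by over 1.5 times. The number of arrays and the signal over background limit what can be called, and the cause of each change below was not tested, except that fewer arrays or genes entered some fits.

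Leaving out each array gave 292 to 437 for control 100 against 30, 0 to 75 for control 145 against 100, 7 to 514 for EB 30, 7 to 2717 for EB 100, 6 to 221 for EB 145 and 0 to 33 for T+E 100. Further ranges were 53 to 177 for T+E 145, 706 to 5752 for EB+T+E 100, 5201 to 8559 for EB+T+E 145, 8 to 5562 for EB+T+E against T+E 100, 2346 to 5733 for EB+T+E against T+E 145 and 22 to 1180 for EB+T+E against EB 100. Further ranges were 2781 to 6060 for EB+T+E against EB 145, 0 to 351 for interaction 100, 44 to 665 for interaction 145, 0 to 431 for EB 100 minus 30, 0 to 4 for EB 145 minus 100 and 1 to 12 for T+E 145 minus 100. Further ranges were 12 to 289 for EB+T+E 145 minus 100. Where an arm then held 2 arrays the shared spread was used.

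Counts that moved by over 1.5 times were, with normexp, 76 for EB 30, 76 for EB 100, 30 for EB 145, 24 for T+E 100, 1768 for EB+T+E 100 and 399 for EB+T+E against T+E 100. It also gave 187 for EB+T+E against EB 100, 1 for EB 100 minus 30 and 1 for T+E 145 minus 100. Quantile scaling gave 152 for T+E 145, 2 for EB 100 minus 30 and 144 for EB+T+E 145 minus 100. With no filter they were 264 for EB 100, 2 for T+E 145 minus 100 and 47 for EB+T+E 145 minus 100. A filter of 17 arrays gave 6 for EB 30, 19 for T+E 100, 47 for T+E 145, 25 for interaction 145, 3 for EB 100 minus 30 and 0 (778) for T+E 145 minus 100. It also gave 2 for EB+T+E 145 minus 100. Slide as a block gave 1605 for EB 100, 32 for EB 145, 81 for T+E 100, 1588 for EB+T+E against T+E 100, 19 for EB 100 minus 30 and 21 for T+E 145 minus 100. It also gave 33 for EB+T+E 145 minus 100. The mean of all probes gave 20 for EB 30. The authors' deposited table gave 137 for T+E 145. Array weights gave 4799 for control 100 against 30, 3 for control 145 against 100, 5118 for EB 30, 3488 for EB 100, 2091 for EB 145 and 1847 for T+E 100. It also gave 954 for T+E 145, 4824 for EB+T+E 100, 2998 for EB+T+E against T+E 100, 10637 for EB+T+E against T+E 145, 10679 for EB+T+E against EB 145 and 117 for interaction 100. It also gave 4305 for interaction 145, 606 for EB 100 minus 30, 356 for T+E 145 minus 100 and 906 for EB+T+E 145 minus 100. With only the groups compared, counts were 2232 for control 100 against 30, 17 for EB 30, 0 (4120) for EB 100, 0 (4131) for EB 145, 248 for T+E 100 and 23 for T+E 145. It also gave 0 (3649) for EB+T+E 100, 0 (2165) for EB+T+E against T+E 100, 0 (988) for EB+T+E against EB 100, 3559 for EB+T+E against EB 145, 278 for interaction 145 and 0 (2000) for EB 100 minus 30. It also gave 0 (2150) for T+E 145 minus 100. The ventral product covariate gave 15 for T+E 100, 249 for EB+T+E against EB 100, 2610 for EB+T+E against EB 145, 3 for EB 100 minus 30, 1 for T+E 145 minus 100 and 7 for EB+T+E 145 minus 100. Other tissue covariates gave 319 for control 100 against 30, 37 for EB 30, 0 (1127) for EB 145, 242 for T+E 100, 556 for EB+T+E 100 and 2907 for EB+T+E 145. It also gave 0 (3313) for EB+T+E against T+E 100, 2483 for EB+T+E against T+E 145, 1286 for EB+T+E against EB 100, 14 for interaction 100, 93 for interaction 145 and 10 for EB 100 minus 30. It also gave 1 for EB 145 minus 100, 29 for T+E 145 minus 100 and 44 for EB+T+E 145 minus 100. The fit without the 2 control arrays gave 347 for control 100 against 30, 1 for control 145 against 100, 47 for EB 100, 2 for EB 145, 0 (1504) for T+E 100 and 53 for T+E 145. It also gave 1635 for EB+T+E 100, 56 for interaction 145, 2 for EB 100 minus 30, 2 for T+E 145 minus 100 and 9 for EB+T+E 145 minus 100.

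Replicate number as a block gave 375 for EB 100, 70 for EB 145, 90 for interaction 145 and 45 for EB+T+E 145 minus 100. Same-numbered arrays deviated together with r from -0.444 to 0.458 over 40 pairs, 12 above 0.1. In 0 of 13 comparisons was every pair above 0.1, which leaves pairing by number open.

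Array weights also turned the balance to 2434 higher and 2365 lower for control 100 against 30, 1065 and 1026 for EB 145 and 1986 and 2319 for interaction 145. Fry called 79 of the 513 list tests, 73 of them among the 232 called by camera and 33 among the 83 of these against controls. Genes called at both adult ages with EB numbered 2 higher and 4 lower with normexp, 6 higher and 9 lower with slide as a block, and 6 lower with no filter. For T+E they were 6 higher and 1 lower with the filter of 17 arrays and 1 lower with normexp. With EB+T+E they were 755 lower with a 2-fold minimum and 650 with normexp. The correlation across genes for EB was 0.569 with normexp, 0.495 with quantile scaling, 0.455 with no filter, 0.623 with the filter of 17 arrays and 0.461 with slide as a block. For EB+T+E it was 0.577 with no filter and 0.725 with the filter of 17 arrays. Single arrays left out gave 0.472 to 0.534 for EB, 0.075 to 0.243 for T+E and 0.529 to 0.684 for EB+T+E.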

Other observations

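The counts over other splits of the arrays were planned, and the genes below were read after the results were seen. With EB+T+E at PND 100 members of developmental signalling stood at -1.64 to -2.45 (SE 0.35 to 0.58, adjusted p 0.00193 to 0.00724) for Bmp7, Foxa1, Fgfr2 and Wif1, in a list that did not pass as a whole (median -0.12, adjusted p = 0.37).

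Other splits of the arrays into groups of the same sizes show how often as many genes were called, with no adjustment over the 19 comparisons. The share was under 0.05 for EB at PND 145 (133 genes, highest other split 5, 1 of 35 splits as large), but limma called 6 without control 2, 10 without EB 3 and 0 (4131 at an unadjusted p under 0.05) with only these groups. EB+T+E against EB at PND 145 (5350, 3505) also gave 1 of 35, the least possible share. So did controls at PND 100 against PND 30 (523, 103), and this alone does not exclude chance. Chance was not excluded for EB at PND 30 (11, 529, 3 of 35). Splits over 4 groups mix differences between groups and cannot judge chance. They gave 4 of 100 for the EB effect at PND 100 minus PND 30 (5, 1150). For the T+E effect at PND 145 minus PND 100 they gave 3 (6, 40). It was 7 for the interaction at PND 145 (180, 1293) and 12 for the EB+T+E effect between adult ages (76, 10294). With a count of 0 every split is as large, so the 100 of 100 for the interaction at PND 100 (highest other 3937) and the EB effect at PND 145 minus PND 100 (5) say nothing of chance. With 3 against 3 arrays the 10 splits are too few for a share under 0.05. The real and highest other counts were 627 and 2 for EB at PND 100, 45 and 5 for T+E at PND 100 and 89 and 1 for T+E at PND 145. They were 2943 and 140 for EB+T+E at PND 100, 8252 and 9 for EB+T+E at PND 145, 4992 and 17 for EB+T+E against T+E at PND 145, and 0 and 1 for the adult controls. For EB+T+E at PND 100 they were 935 and 1324 against T+E (3 of 10 splits) and 400 and 4028 against EB (4 of 10). For EB at PND 30 and EB+T+E against EB at PND 100, splits that called several times the real count may point to another structure of these arrays, which was not tested.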
